A study of Rattus norvegicus with 8 samples.

How the data were processed

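Oesophageal tissue of rats was profiled on Affymetrix expression arrays. Per the labels' protocols, every rat received subcutaneous injections of N-nitrosomethylbenzylamine (NMBA), a nitrosamine that induces squamous tumours of the rat oesophagus, at 0.35 mg/kg, 3 times per week for 5 weeks, and was fed either a riboflavin-normal or a riboflavin-deficient diet until it was killed at week 25. The tissue was fixed in paraformaldehyde and embedded in paraffin, the regions of interest were isolated, and total RNA was amplified with a whole-transcriptome kit made for fixed tissue and labelled with biotin, per the labels' protocols. The 8 arrays came from 4 animals, 2 per diet, each giving 1 array of epithelial neoplasia and 1 array of adjacent normal tissue. Group and animal were taken from the titles, and the sample descriptions carried the same animal code for both tissues of a pair.

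The authors deposited log2 values for each probe set, made with Affymetrix Expression Console and RMA (robust multi-array average, which corrects background, normalises between arrays and summarises probes), per the submitters' processing notes. Their versions and the genome build were not given in the sources used here, so no coordinates are reported. The deposited table held 70580 probe sets on 8 arrays. A single gene symbol was paired with 23446 of them in the platform annotation, several symbols with 505, and the remaining 46629 were unnamed here or were controls. Symbols were updated through Entrez IDs, by which 22077 probe sets matched and 1 symbol changed. For 1182 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which left 22093 genes. Values ran from 2.43 to a ceiling of 19.93 (999952 on the linear scale), with a median of 4.98. The ceiling was met on at least 1 array by 16 genes, among them the keratinocyte genes Krt4, Krtdap, Sprr2b, Sprr3 and Stfa3, and differences involving such values are bounds. Over all probe sets, 468 were at the ceiling on riboflavin-normal adjacent normal replicate 2, against 1479 to 1748 on the other arrays. On each array only 9 to 15 of the genes tested were among them. The cause of this difference is not known. Slc52a1, Flad1 and Krt5, which had been chosen in advance, were not paired with a usable probe set here.

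Comparisons were fitted with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with lmFit and eBayes. Neoplasia was compared with adjacent normal tissue in a model with a term per animal and a neoplasia term per diet, which left 2 residual degrees of freedom. From it came the mean neoplasia effect, the effect in each diet, and the difference between diets. Both diet comparisons, within neoplasia and within adjacent normal tissue, used a mean per group, which left 4 residual degrees of freedom, since animal and diet cannot be separated. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of genes and lists are from limma throughout, and those of the correlations with array quality from exact permutation. A tissue difference for 1 gene over 4 pairs cannot reach an exact p below 0.125, and 2 arrays against 2 cannot go below 0.333, so single genes were tested only through the limma fits, which pool the spread across genes.

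A set of 33 gene lists covering epithelial differentiation, immune cells, stroma, muscle, neighbouring tissues, flavin biology, metabolism, stress responses and RNA quality was tested with camera (preset correlation between genes of 0.01), adjusted over the 33 lists of a comparison. Of 1061 list entries, 986 matched a measured gene. Each list was also tested with an estimated correlation and with fry, and its members were adjusted over the list alone. Camera asks whether the members of a list shifted relative to all other genes, whereas fry asks whether they moved, on balance, in a single direction. A list value is the median log2 difference of its members. Some lists had low signal, with medians per array near or below the table's median of 4.98. These medians ran from 4.4 to 4.7 for neutrophil markers, 4.7 to 5.0 for cytokines, 4.7 to 5.1 for T and NK cells, and 4.8 to 5.0 for proliferation. Small shifts of such lists are shifts at low signal.

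Named genes followed a fixed rule. In each comparison it took up to 10 genes per direction that passed, had the same sign in every pair (or groups that did not overlap) and a group mean at or above the table's median. Places left open went to the genes of lowest unadjusted p under the same conditions. It further took up to 4 members of each list with the smallest unadjusted p, and a panel of riboflavin, inflammation and epithelial genes. As no gene passed over all genes in any comparison, every named gene is described by its value and SE, and the text says where a gene passed when adjusted over its list alone. Predicted genes were skipped, and a selection from those named by the rule is printed.

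Array quality was measured as the separation of 399 probe sets marked as positive controls from 1153 marked as negative controls, given as the area under the receiver operating curve. What the platform's positive and negative marks stand for was not given in the sources used here, so what a unit of the measure stands for is open. It is used as a numeric scale in correlations, slopes and the quality covariate, which assumes a linear relation. Slopes with a group left out were computed after the data were seen. Of the controls marked negative, 4 were at the ceiling on every array. Scan dates, batches and RNA integrity values were not used here. Fixed tissue yields fragmented RNA, and the number of arrays limits the precision of every value. The pairing was taken from the shared animal codes. The deviations of paired arrays from their group means correlated at 0.188 for the riboflavin-normal pairs and 0.157 for the riboflavin-deficient pairs, and the consensus correlation within animals from duplicateCorrelation was 0.06. Replicate arrays within a group correlated between 0.916 and 0.973.

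Groups, models, thresholds, lists, the naming rule and the alternatives were fixed before the data were examined, except for 3 alternatives added afterwards: array quality as a covariate, quantile normalisation for the lists, and animal as a random effect for the lists in the diet comparisons. The alternatives chosen in advance were no animal block, animal as a random effect, array weights, an intensity trend with a robust prior, cyclic loess and quantile normalisation on top of the deposited values, the upper 50 percent of genes by mean, the mean of all probe sets of a gene, every probe set, unadjusted p under 0.05 with at least a 2-fold change, only the 4 arrays of a tissue for the diet comparisons, and leaving out each animal or array. Each model was tested on simulated data with the real gene means and with independent noise drawn from the fitted spread, in 22093 genes. For the mean neoplasia effect, 10% of 50 genes changed 2-fold were called, 78% at 4-fold and 90% at 8-fold. For the difference between diets no gene was called at 2-fold or 4-fold, 28% were at 8-fold and 70% at 16-fold. In the riboflavin-deficient against riboflavin-normal neoplasia comparison the shares were 2%, 82% and 88% at 2-, 4- and 8-fold. Shared array-quality differences were not simulated. Figures were drawn with matplotlib 3.10.9 under python 3.11.15.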

Results

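The data comprised 8 arrays of rat oesophagus after NMBA treatment. They formed 4 groups of 2 arrays, namely adjacent normal tissue and epithelial neoplasia from rats on a riboflavin-normal diet, and the same tissues from rats on a riboflavin-deficient diet. Riboflavin is the precursor of the flavin cofactors FMN and FAD. Each of the 4 animals gave both tissues, so tissues were compared within animals and diets between animals. The series title names riboflavin deficiency and genes associated with inflammation as its subject. After reduction to a single probe set per gene, 22093 genes were measured, and arrays correlated with each other at 0.916 to 0.974.

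The arrays differed in how well positive and negative control probe sets separated. The area under the curve was 0.577 and 0.757 in riboflavin-normal adjacent normal tissue, 0.696 and 0.694 in riboflavin-normal neoplasia, 0.659 and 0.598 in riboflavin-deficient adjacent normal tissue, and 0.617 and 0.600 in riboflavin-deficient neoplasia (replicates 1 and 2). Group means were 0.667, 0.695, 0.628 and 0.608. The first principal component held 50.8% of the variance and followed this measure (Pearson r = 0.99, exact permutation p = 9.92e-05, adjusted 0.000496; Spearman rho = 0.95, exact permutation p = 0.00114, adjusted 0.0057; 8 arrays). So did the median of the cytosolic ribosomal protein genes (r = 0.99, exact permutation p = 0.000174, adjusted 0.000579; rho = 0.93, exact permutation p = 0.00223, adjusted 0.00744). Without the 2 arrays farthest from the median, r was 0.97 and 0.98. The SD of the gene values on an array followed the separation too (r = 0.99, adjusted permutation p = 0.000496). By rank, rho was 0.95 (adjusted permutation p = 0.0057), and r was 0.98 without those 2 arrays. This SD ran from 1.329 in riboflavin-normal adjacent normal replicate 1 to 1.751 in replicate 2, so values were less spread on arrays of lower separation. Of the 10 relations computed, the oxidative phosphorylation list also passed for r (r = 0.91, adjusted permutation p = 0.00496; rho = 0.79, adjusted permutation p = 0.0698). Without those 2 arrays its r was 0.90. The extracellular matrix list passed for r as well (r = 0.78, adjusted permutation p = 0.0284; rho = 0.67, adjusted permutation p = 0.138), with r = 0.62 without them. The skeletal muscle (r = 0.73), squamous differentiation (r = 0.72), stress keratinocyte (r = 0.39), adipocyte (r = -0.22) and proliferation (r = -0.21) lists did not pass, with adjusted permutation p from 0.0608 to 0.69. Without the 2 arrays farthest from the median these r were 0.65, 0.83, 0.72, -0.10 and 0.67, so a relation with quality is not excluded for the skeletal muscle, squamous, stress keratinocyte and proliferation lists. With 2 arrays per group, no correlation was computed within a single group. Pooled over the replicate differences of the 4 groups, the slope of the ribosomal median was 1.32 (SE 0.1) per 0.1 of control separation. The riboflavin-normal adjacent normal group held 89% of the squared differences in separation, and without it the slope was 0.87 (SE 0.11).

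**Figure D1:**
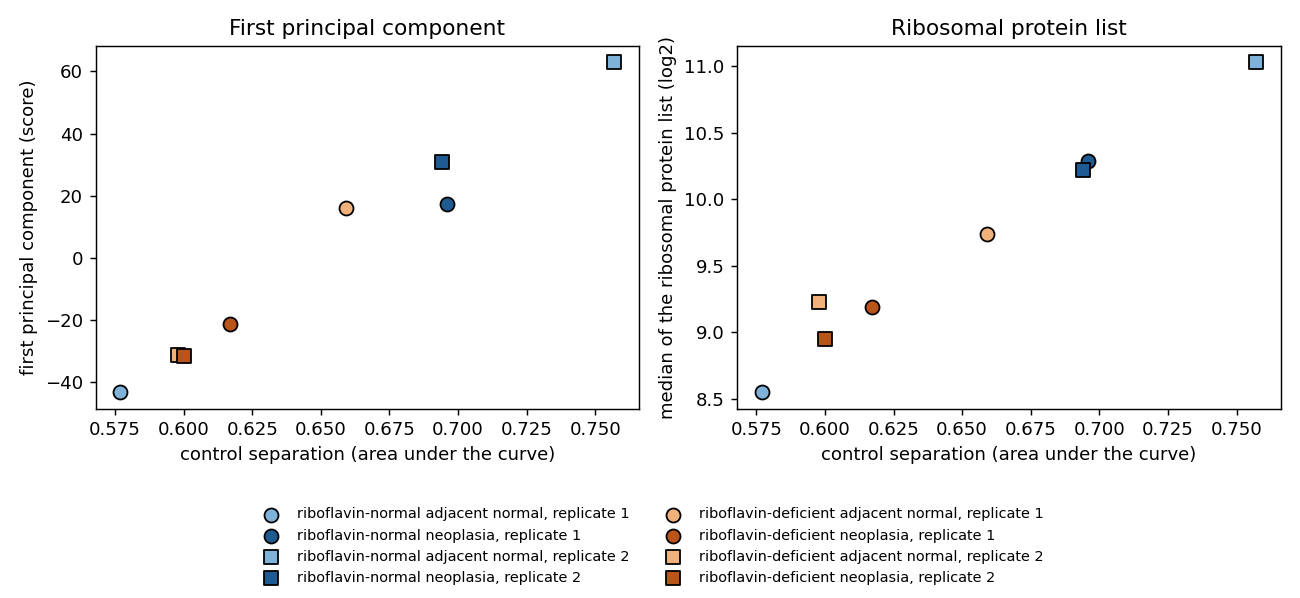
Score on the first principal component (left) and median log2 value of the cytosolic ribosomal protein genes (right) against the control separation (area under the curve), 1 point per array, coloured by diet and tissue with the replicate as the shape. Both rose with the separation, from the riboflavin-normal adjacent normal arrays of replicate 1 at 0.577 to replicate 2 at 0.757, and both riboflavin-deficient neoplasia arrays lay at or below 0.617.

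The first comparison asked how neoplasia differed from the adjacent normal tissue of the same animal over both diets. S100a8 and S100a9, the subunits of the calcium-binding protein calprotectin made by neutrophils and by stressed squamous epithelium, were higher in neoplasia in each of the 4 pairs. The mean log2 difference was 2.10 for S100a8 (SE 0.37, pair values 1.02 to 3.17) and 1.14 for S100a9 (SE 0.12, pair values 0.64 to 1.47). Stfa2, a stefin-family inhibitor of cysteine proteases, was 1.08 higher (SE 0.16), with 2.34 and 1.61 in the riboflavin-normal pairs and 0.09 and 0.28 in the riboflavin-deficient pairs. These 3 of the 17 stress keratinocyte genes passed when adjusted over the list alone (limma adjusted p = 0.0158, 0.00556 and 0.0127). S100a8 and S100a9 also passed among the 20 neutrophil markers (limma adjusted p = 0.0279 and 0.00654). At the other end, 4 named genes of striated muscle, picked under a rule that asked for a shared sign, were lower in every pair. Of the 34 markers in the skeletal muscle list only 2 were. The named genes were Lmod2, which nucleates actin filaments (-1.30, SE 0.18), the Z-disc protein gene Pdlim3 (-1.25, SE 0.19), Klhl41 (-1.23, SE 0.22) and the muscle caveolin gene Cav3 (-0.80, SE 0.11). Bex1 was lower by the largest amount among the named genes (-2.35, SE 0.43, pair values -3.50, -0.94, -2.49 and -2.45). None of these passed over all genes.

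As a group, the stress keratinocyte genes shifted upward, with 15 of 17 members higher and a median of 0.60 (camera adjusted p = 2.6e-09; adjusted p = 0.85 with an estimated correlation). The pair medians were 1.65 and 0.39 in the riboflavin-normal and -0.18 and 0.28 in the riboflavin-deficient pairs. The list stayed called with any animal left out, at 0.25 without riboflavin-normal replicate 1 and 0.35 without riboflavin-deficient replicate 2. Il36g, an epithelial cytokine of the interleukin-1 family in the same list, was 1.33 higher (SE 0.34). Skeletal muscle markers shifted downward, all 34 being lower in the mean of the pairs with a median of -0.63 (adjusted p = 4.1e-14; adjusted p = 0.85 with an estimated correlation). Myoz1 (-1.53, SE 0.44) and the fast troponin gene Tnni2 (-1.03, SE 0.33) were examples. The pair medians of that list were 0.00 and -1.78 in the riboflavin-normal and -1.27 and 0.24 in the riboflavin-deficient pairs. Without riboflavin-normal replicate 2 its median was -0.26 and the call was lost. It was -0.25 without riboflavin-deficient replicate 1, and -1.12 and -1.13 without riboflavin-normal replicate 1 and riboflavin-deficient replicate 2. Suprabasal squamous differentiation genes shifted upward (median 0.30, 43 of 49 higher, adjusted p = 2.8e-06; adjusted p = 0.85 with an estimated correlation), with pair medians of 1.90, 0.20, -0.91 and 0.16. Their median was 0.00 without riboflavin-normal replicate 1 and 0.01 without riboflavin-deficient replicate 2, either of which ended the call, and 0.77 and 0.75 without the other animals. Proliferation genes (median 0.09, 38 of 49 higher, adjusted p = 0.00106; Top2a, a topoisomerase of dividing cells, 0.37 with SE 0.14) and neutrophil markers (median 0.03, 13 of 20 higher, adjusted p = 0.0109) shifted upward by small amounts. Both had an adjusted p = 0.85 with an estimated correlation. Both calls were lost without riboflavin-normal replicate 2, at medians of 0.03 and -0.05. The neutrophil call was also lost without riboflavin-deficient replicate 1, at 0.02, and its median was 0.14 and 0.07 without the other 2 animals. The neutrophil list includes S100a8 and S100a9, and its mean of 0.21 stood above its median of 0.03. The call may thus rest largely on these 2 genes, which are also in the stress keratinocyte list. The list was not tested without them.

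Oxidative phosphorylation (median -0.24, 37 of 40 lower, adjusted p = 1.45e-06), smooth muscle (median -0.37, 15 of 16 lower, adjusted p = 0.000651) and extracellular matrix and fibroblast genes (median -0.20, 30 of 34 lower, adjusted p = 0.000899) shifted downward. They had adjusted p = 0.85, 0.85 and 0.89 with an estimated correlation. The respiratory complex I gene Ndufb9 (-0.54, SE 0.21), the calcium store gene Casq2 (-1.19, SE 0.49) and the collagen gene Col1a1 (-0.34, SE 0.18) were the members named. Without riboflavin-normal replicate 2 the calls of oxidative phosphorylation and smooth muscle were lost, at medians of -0.02 and 0.01. The extracellular matrix list was then called in the opposite direction, at 0.12 (adjusted p = 0.000203). Smooth muscle was lost as well without riboflavin-deficient replicate 1 (-0.18), and extracellular matrix without riboflavin-deficient replicate 2 (-0.20). Without riboflavin-normal replicate 1 the 3 medians were -0.50, -0.79 and -0.59. Oxidative phosphorylation stood at -0.11 without riboflavin-deficient replicate 1, and smooth muscle at -0.74 without riboflavin-deficient replicate 2. In that riboflavin-normal pair the control separation differed by -0.063 between neoplasia and adjacent normal tissue, against 0.119, -0.042 and 0.002 in the other pairs.

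By limma, 0 of 22093 genes passed for the mean neoplasia effect. At an unadjusted p under 0.05 there were 485 genes, 272 higher and 213 lower, where 1105 would be reached by chance. In all 4 pairs the same direction was seen for 1744 genes, or 7.9%, where chance gives 12.5%. Camera called 8 of 33 lists, and 0 with an estimated correlation. Fry called 1, the NF-kB pathway list (median 0.04, 19 of 25 higher, fry adjusted p = 0.0461). Its pair medians were -0.01 and 0.13 in the riboflavin-normal and -0.05 and -0.04 in the riboflavin-deficient pairs. No member was higher in all 4 pairs. Camera did not call that list (adjusted p = 0.132; adjusted p = 0.85 with an estimated correlation).

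**Figure D2:**
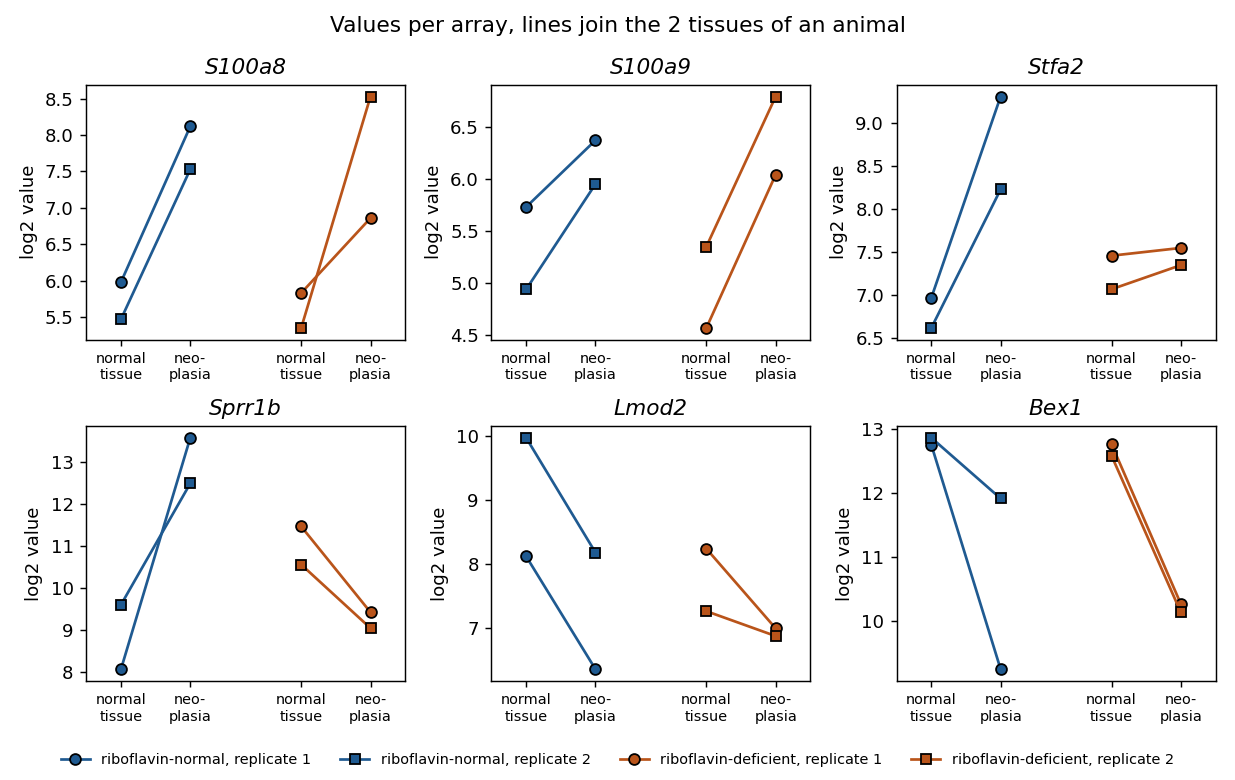
Log2 values of S100a8, S100a9, Stfa2, Sprr1b, Lmod2 and Bex1 on each array, with lines joining the adjacent normal tissue and neoplasia of an animal, blue for the riboflavin-normal and orange for the riboflavin-deficient diet. S100a8 was higher in neoplasia by 1.02 to 3.17 in all 4 pairs, whereas Sprr1b was higher by 5.53 and 2.90 in the riboflavin-normal pairs and lower in the riboflavin-deficient pairs (-2.05 and -1.52).

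In rats on the riboflavin-normal diet, neoplasia showed more transcripts of the cornifying squamous epithelium. Sprr1b and Sprr2d, which encode cross-linked precursors of the cornified envelope, were 4.21 (SE 0.64) and 3.23 (SE 0.95) higher on the log2 scale in neoplasia. The protease inhibitor gene Csta was 4.24 higher (SE 1.09), and the desmosomal cadherin gene Dsg1 was 2.66 higher (SE 0.78; 2 pairs each). The suprabasal squamous list had 46 of 49 members higher and a median of 0.99 (camera adjusted p = 4.64e-15; adjusted p = 0.69 with an estimated correlation), from pair medians of 1.90 and 0.20. With the first of these pairs left out, the call was lost. In that pair control separation differed by 0.119 between neoplasia and adjacent normal tissue, against -0.063 in the other. A relation of this shift with array quality is therefore not excluded. The stress keratinocyte list had 16 of 17 members higher and a median of 1.57 (adjusted p = 3.27e-13; adjusted p = 0.69 with an estimated correlation). Its pair medians were 1.65 and 0.39, both above 0. A call from a single pair is weak evidence, since the ribosomal list was called upward with both pairs and downward with 1 of them, as given below. Among the stress keratinocyte genes 6 passed when adjusted over the list alone. Stfa2 was 1.98 higher (SE 0.23, limma adjusted p = 0.0082), and the serine protease inhibitor gene Serpinb3 was 1.54 higher (SE 0.27, limma adjusted p = 0.0249). Il36g (2.06), S100a8 (2.10), S100a9 (0.83) and Serpinb2 (1.77) each had a limma adjusted p of 0.0317.

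In the riboflavin-normal pairs proliferation genes also shifted upward (median 0.14, 39 of 49 higher, adjusted p = 5.18e-05; adjusted p = 0.69 with an estimated correlation). Mki67, a marker of cycling cells, was 0.91 higher (SE 0.25), the kinesin gene Cenpe 0.66 higher (SE 0.16) and Top2a 0.70 higher (SE 0.20). NRF2 targets and oxidative stress genes shifted upward (median 0.12, 31 of 42 higher, adjusted p = 0.000357; adjusted p = 0.69 with an estimated correlation). The glutathione genes Gclc, Gpx2 and Gstm1 were 0.73, 1.76 and 1.36 higher (SE 0.17, 0.43 and 0.33). Smaller upward shifts were called for the EGFR, Wnt and Notch list (median 0.10, 33 of 45), p53 targets (0.15, 18 of 28), basal keratinocyte markers (0.17, 16 of 21) and cytokines and chemokines (0.07, 25 of 36). Their camera adjusted p was 0.00712, 0.0335, 0.034 and 0.034, and each had an adjusted p = 0.69 with an estimated correlation. Examples were the cell-cycle inhibitor gene Cdkn1a (0.68, SE 0.18), the basal transcription factor gene Tp63 (1.50, SE 0.43), Trim29 (2.14, SE 0.81) and the monocyte chemokine gene Ccl2 (1.21, SE 0.27). Among single genes outside the lists, the deubiquitinase gene Cyld (1.51, SE 0.21), the epithelial transcription factor gene Klf5 (1.71, SE 0.26), Ell2 (1.61, SE 0.23), Bhlhe40 (1.04, SE 0.15), Pdcd10 (1.27, SE 0.15) and the small nucleolar RNA Snora20 (3.35, SE 0.41) were higher in both pairs.

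Muscle and stromal lists shifted downward in these pairs. They were skeletal muscle (median -0.80, 34 of 34 lower, adjusted p = 5.19e-11), smooth muscle (-0.77, 16 of 16, adjusted p = 1.87e-06), extracellular matrix (-0.42, 30 of 34, adjusted p = 1.64e-05), oxidative phosphorylation (-0.29, 29 of 40, adjusted p = 0.000555) and nerve and Schwann cell markers (-0.11, 14 of 17, adjusted p = 0.0304). With an estimated correlation each had an adjusted p = 0.69. Lmod2 (-1.79, SE 0.25), Pdlim3 (-1.79, SE 0.27), Klhl41 (-1.87, SE 0.31), Cav3 (-0.99, SE 0.16), the muscle ubiquitin ligase gene Trim63 (-1.02, SE 0.26), the enteric actin gene Actg2 (-1.19, SE 0.60) and the matrix protein gene Postn (-0.71, SE 0.17) were lower. Without replicate 2 the medians of the first 4 of these lists were 0.00, 0.03, 0.19 and 0.14, so these shifts rested on a single pair. In the pair that remained, extracellular matrix (adjusted p = 0.000434) and oxidative phosphorylation (adjusted p = 0.0261) were called upward. Without replicate 1 those 4 medians were -1.78, -1.99, -1.23 and -0.77. Ribosomal protein genes shifted upward (median 0.28, 42 of 51 higher, adjusted p = 0.000467; adjusted p = 0.69 with an estimated correlation), with Rps28 1.37 higher (SE 0.48). Their pair medians were 1.05 and -0.38, in the order of the control separation differences of 0.119 and -0.063, and without replicate 1 the list was called downward (adjusted p = 2.15e-10). Its call was lost under cyclic loess (0.12, adjusted p = 0.119), quantile normalisation (0.17, adjusted p = 0.13) and control separation as a covariate (0.05, adjusted p = 0.729), a covariate chosen after the data were seen. These 3 settings also ended the calls of the basal keratinocyte and p53 lists, and loess and the covariate that of the nerve list. Among the upper 50 percent of genes by mean, the basal keratinocyte, p53, nerve and EGFR, Wnt and Notch lists were not called, nor was the p53 list without the animal block. With the covariate the cytokine, extracellular matrix, smooth muscle and oxidative phosphorylation medians were 0.16, -0.75, -1.23 and -0.44, all called. Without replicate 1 the basal keratinocyte list stood at -0.06, the NRF2 list at 0.01, the nerve list at 0.00, the p53 list at 0.11 and the EGFR, Wnt and Notch list at 0.16, none of them called, and proliferation at 0.22 and cytokines at 0.21 were called. Without replicate 2 proliferation stood at 0.07 and cytokines at 0.00, neither of them called, and basal keratinocyte (0.43), NRF2 (0.27) and nerve (-0.24) lists were called. With limma 0 genes passed, and 806 lay at an unadjusted p under 0.05 (566 higher, 240 lower; 1105 by chance). Camera called 14 lists, 0 with an estimated correlation and 0 by fry.

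In rats on the riboflavin-deficient diet, S100a9 was 1.46 higher in neoplasia (SE 0.17, 1.47 and 1.45 in the 2 pairs). It passed when adjusted over the stress keratinocyte list alone (limma adjusted p = 0.00887) and over the neutrophil list alone (limma adjusted p = 0.0104). S100a8 was 2.10 higher (SE 0.52) and did not pass. Sprr1b was lower in neoplasia, at -1.78 (SE 0.64), and the squamous list shifted downward (median -0.39, 35 of 49 lower, camera adjusted p = 0.00719; adjusted p = 1 with an estimated correlation). Its pair medians were -0.91 and 0.16, so without replicate 1 it was called upward (adjusted p = 0.00389). The call was lost under cyclic loess (-0.34, adjusted p = 0.0879), quantile normalisation (-0.34, adjusted p = 0.0987) and the quality covariate (-0.17, adjusted p = 0.167). Chaperone and immediate early genes also shifted downward (median -0.18, 22 of 25 lower, adjusted p = 0.000218; adjusted p = 1 with an estimated correlation). That list was included as a gauge of tissue handling. The chaperone genes Hsp90aa1 (-0.93, SE 0.17) and Hspa8 (-1.58, SE 0.63) and the transcription factor gene Jun (-0.88, SE 0.34) were lower in both pairs.

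Adipocyte markers shifted upward (median 0.27, 16 of 19 higher, adjusted p = 2.45e-05; adjusted p = 1 with an estimated correlation), but pair medians were 0.53 and 0.00, and the call was lost without replicate 1. Adipoq, the adipokine adiponectin, was 1.82 higher (SE 0.93) through replicate 1 alone (3.79 against -0.16). Cidec, a lipid droplet protein gene, was 0.86 higher (SE 0.42), and Cfd, which encodes adipsin, was 0.57 higher (SE 0.19) with 0.72 and 0.43 in the pairs. Skeletal muscle (median -0.51, 28 of 34 lower, adjusted p = 0.000754), ribosomal protein (-0.29, 46 of 51, adjusted p = 0.000218), oxidative phosphorylation (-0.16, 34 of 40, adjusted p = 0.00719) and NRF2 genes (-0.11, 29 of 42, adjusted p = 0.00719) shifted downward. Each had an adjusted p = 1 with an estimated correlation. Without replicate 1 skeletal muscle was called upward, at 0.24 (adjusted p = 0.00619), and the other 3 medians were -0.01, 0.00 and -0.02, none of them called. Without replicate 2 the 4 medians were -1.27, -0.54, -0.35 and -0.19, all called. The quality covariate ended the calls of skeletal muscle (-0.34), oxidative phosphorylation (-0.07) and NRF2 genes (-0.07), and left ribosomal genes called at -0.13. Both further normalisations, and removal of the animal block, also ended the oxidative phosphorylation and NRF2 calls. Among the upper 50 percent of genes by mean, oxidative phosphorylation was not called. Examples were the oxygen carrier gene Mb (-2.05, SE 1.23), Myoz1 (-1.20, SE 0.62), Rpl35 (-0.71, SE 0.24), Rpl19 (-0.92, SE 0.40), Cox7b (-0.44, SE 0.18), Gstm1 (-1.56, SE 0.33) and Gclm (-0.65, SE 0.18). Neutrophil markers (median 0.03, 15 of 20 higher, adjusted p = 0.044) and extracellular proteases (0.07, 17 of 24 higher, adjusted p = 0.0467) shifted upward, with adjusted p = 1 for both with an estimated correlation. Both calls were lost without replicate 1, at 0.06 and 0.03. The protease call was also lost without replicate 2 (0.12), without the block and in the upper 50 percent of genes, and the neutrophil call without either riboflavin-normal animal, which changed only the estimate of the spread. Cyclic loess and quantile normalisation ended both calls, and the quality covariate that of the neutrophil markers (0.00). The neutrophil list, with a mean of 0.22, again includes S100a8 and S100a9 and was not tested without them.

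Among the genes of lowest unadjusted p in the riboflavin-deficient pairs, the peroxisome assembly gene Pex19 (1.25, SE 0.22), the helicase gene Ddx28 (0.81, SE 0.15), Ogfrl1 (0.86, SE 0.18) and Tmem203 (2.14, SE 0.46) were higher. Tmem154 (-1.64, SE 0.26), the translation termination factor gene Gspt1 (-1.12, SE 0.20), Rab22a (-0.84, SE 0.16), the phosphatase gene Acp1 (-0.85, SE 0.24) and Birc5, an inhibitor of apoptosis expressed in mitosis (-0.78, SE 0.21), were lower. By limma 0 genes passed, and 425 lay at an unadjusted p under 0.05 (197 higher, 228 lower; 1105 by chance). Camera called 9 lists, 0 with an estimated correlation and 0 by fry.

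**Figure D3:**
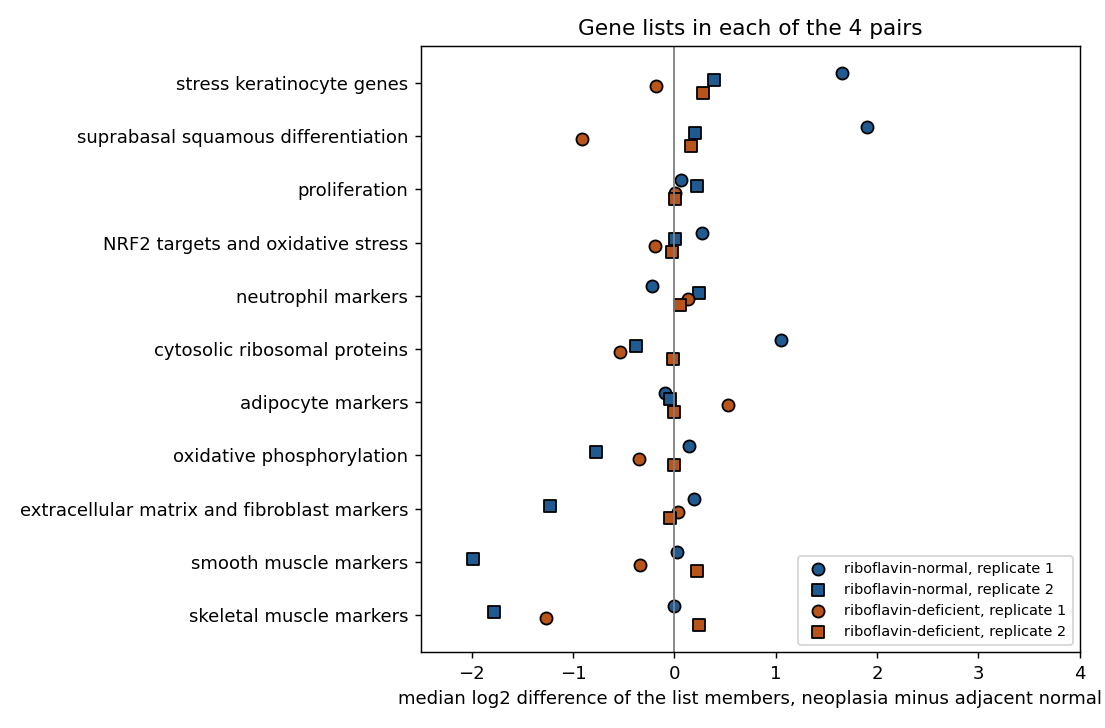
Median log2 difference between neoplasia and adjacent normal tissue of the members of 11 gene lists, 1 point per animal, blue for the riboflavin-normal and orange for the riboflavin-deficient diet, circles for replicate 1 and squares for replicate 2. Pair medians of the skeletal muscle list ranged from -1.78 to 0.24, and those of the squamous list from -0.91 to 1.90.

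The difference between diets of the neoplasia effect asked directly whether riboflavin deficiency altered the tissue contrast. Among the squamous genes, Sprr1b differed by -6.00 (SE 0.90), Csta by -5.96 (SE 1.54) and the envelope protein gene Scel by -3.05 (SE 0.91). All 3 were higher in neoplasia on the riboflavin-normal diet and lower in the mean on the deficient diet. The squamous list shifted by a median of -1.38, with 44 of 49 members below 0 (camera adjusted p = 8.71e-13; adjusted p = 0.68 with an estimated correlation). The stress keratinocyte list shifted by -1.45, with 15 of 17 below 0 (adjusted p = 3.76e-06; adjusted p = 0.68 with an estimated correlation). Over all leave-outs of an animal these medians ran from -2.34 to -0.63 and from -1.94 to -0.40, and both lists stayed called. They stayed called with the quality covariate too, at -0.87 and -0.94. In this model the covariate leaves fewer than the 2 residual degrees of freedom of the main fit. Its slope rests mainly on the riboflavin-normal pairs, whose separation differed by 0.119 and -0.063, against -0.042 and 0.002 in the riboflavin-deficient pairs. The adjusted values are therefore imprecise and do not exclude array quality. In the stress list Stfa2 (-1.79, SE 0.33), Serpinb3 (-1.88, SE 0.38), Serpinb2 (-2.55, SE 0.59) and the connexin 26 gene Gjb2 (-1.65, SE 0.38) passed when adjusted over the list alone, each at a limma adjusted p of 0.0378. For S100a8 the difference was 0.00 (SE 0.73).

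Of the 12 measured riboflavin uptake and flavin cofactor genes, Acp1, a phosphatase that can act on flavin mononucleotide, differed by -1.87 (SE 0.34). It passed when adjusted over the list alone (limma adjusted p = 0.0384), although the list as a whole was not called. This adjustment took no account of the other lists and comparisons. NRF2 genes shifted by -0.23 (34 of 42 below 0, adjusted p = 2.48e-05), with Gstm1 at -2.92 (SE 0.47), Gclm at -1.14 (SE 0.26) and Gpx2 at -2.15 (SE 0.60). Ribosomal protein genes shifted by -0.62 (50 of 51 below 0, adjusted p = 7.67e-07; Rpl19 -1.79, SE 0.56). Chaperone and immediate early genes shifted by -0.24 (19 of 25, adjusted p = 0.00402; Hsp90aa1 -1.32, SE 0.24; Egr1 -1.20, SE 0.28). Proliferation genes shifted by -0.11 (37 of 49, adjusted p = 0.00402; Mki67 -1.36, SE 0.35; Birc5 -0.85, SE 0.29). The p53 list shifted by -0.20 (21 of 28, adjusted p = 0.0252; Plk2 -1.06, SE 0.26; Cdkn1a -0.93, SE 0.25). Basal keratinocyte markers (-0.21, 16 of 21, adjusted p = 0.0341) and the EGFR, Wnt and Notch list (-0.12, 32 of 45, adjusted p = 0.0105) shifted the same way. With an estimated correlation each of these 7 lists had an adjusted p = 0.68. Leaving out riboflavin-normal replicate 1 ended the calls of the basal keratinocyte list, whose direction turned at a median of -0.02, and of the NRF2 (-0.16), p53 (-0.13), EGFR, Wnt and Notch (-0.17) and chaperone lists (-0.25). Leaving out riboflavin-deficient replicate 1 ended the basal keratinocyte (-0.18), p53 (-0.07) and EGFR, Wnt and Notch (-0.12) calls, and proliferation was lost without either replicate 2 (-0.03 and -0.12). Medians that stayed called moved as well. Basal keratinocyte, NRF2 and ribosomal lists stood at -0.85, -0.40 and -1.37 without riboflavin-normal replicate 2, and proliferation at -0.24 without riboflavin-normal replicate 1. The ribosomal median was -0.28 and -0.95 without riboflavin-deficient replicates 1 and 2, and the p53 median -0.32 without the latter. The basal keratinocyte and p53 calls were also lost under cyclic loess, quantile normalisation and the quality covariate, which likewise ended the ribosomal (-0.17, adjusted p = 0.0743) and EGFR, Wnt and Notch calls. In the upper 50 percent of genes by mean, the proliferation, basal keratinocyte, p53, EGFR, Wnt and Notch, and chaperone lists were not called.

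Upward differences were called for adipocyte markers (median 0.80, 18 of 19 above 0, adjusted p = 8.32e-05), smooth muscle (0.70, 15 of 16, adjusted p = 0.000633), extracellular matrix (0.38, 27 of 34, adjusted p = 0.00132), skeletal muscle (0.26, 23 of 34, adjusted p = 0.0226) and T and NK cell markers (0.11, 16 of 26, adjusted p = 0.0347). With an estimated correlation the adjusted p = 0.77 for skeletal muscle and 0.68 for the others. Leaving out riboflavin-normal replicate 2 turned smooth muscle to -0.09, extracellular matrix to -0.28 and skeletal muscle to -0.35. Leaving out riboflavin-deficient replicate 2 turned skeletal muscle to -0.42, and leaving out riboflavin-normal replicate 1 turned ribosomal genes to 0.13. Of these turned lists, extracellular matrix (adjusted p = 0.00483), skeletal muscle at -0.42 (adjusted p = 0.0334) and ribosomal genes (adjusted p = 0.00793) were called in the opposite direction. Adipocyte markers were not called without riboflavin-deficient replicate 1 (0.08) or riboflavin-normal replicate 2 (0.53), nor smooth muscle without riboflavin-deficient replicate 2 (0.38). Of the 4 animals left out in turn, T and NK cell markers stayed called only without riboflavin-normal replicate 2 (0.21), and they lost the call under both further normalisations and the quality covariate. With that covariate extracellular matrix, smooth muscle and skeletal muscle were called at 0.84, 1.07 and 0.66, and without riboflavin-normal replicate 1 at 1.25, 1.61 and 1.01. Skeletal muscle was at 1.09 without riboflavin-deficient replicate 1. The fatty acid transporter gene Cd36 (2.57, SE 0.59), Pex19 (1.68, SE 0.31), the ribonuclease gene Rnase1 (1.27, SE 0.26), Ggt5 (1.06, SE 0.23) and the esterase gene Bche (1.95, SE 0.48) were above 0. The growth factor carrier gene Fgfbp1 (-1.82, SE 0.23), the deubiquitinase gene Uchl3 (-3.56, SE 0.47), Ell2 (-2.42, SE 0.33), Pdcd10 (-1.51, SE 0.21) and the fatty acid elongase gene Elovl6 (-1.95, SE 0.28) were below 0.

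By limma 0 genes passed for this difference, and 760 lay at an unadjusted p under 0.05 (224 above and 536 below 0; 1105 by chance). Camera called 14 lists, 0 with an estimated correlation and 0 by fry. Across the 22093 genes, which are not independent replicates, the neoplasia effects of the diets correlated at r = -0.19 (rho = -0.13) and had the same sign in 46%.

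Compared directly between diets, riboflavin-deficient neoplasia had lower values of squamous, basal, ribosomal protein and redox genes than riboflavin-normal neoplasia. The ribosomal list was included as a gauge of RNA quality. With the quality covariate the squamous, ribosomal and NRF2 calls were lost, as given below. Sprr1b was at -3.81 (SE 0.62, 2 against 2 arrays) and passed when adjusted over the list alone (limma adjusted p = 0.0344). Csta was at -3.53 (SE 1.12) and the epidermal lipoxygenase gene Alox12b at -2.77 (SE 0.82). The squamous list had 40 of 49 members lower with a median of -0.82 (camera adjusted p = 2.39e-08; adjusted p = 0.64 with an estimated correlation). Basal keratinocyte markers had 16 of 21 lower with a median of -0.46 (adjusted p = 8.91e-05; adjusted p = 0.55 with an estimated correlation). They included Tp63 (-1.71, SE 0.41), Trim29 (-2.61, SE 0.75) and the integrin gene Itga6 (-1.52, SE 0.47). Stress keratinocyte genes had 14 of 17 lower with a median of -0.75 (adjusted p = 0.000969; adjusted p = 0.55 with an estimated correlation), including Serpinb2 (-1.47, SE 0.44).

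All 51 ribosomal protein genes were lower, with a median of -0.93 (adjusted p = 6.89e-15; adjusted p = 0.64 with an estimated correlation). Rps20 was at -2.30 (SE 0.74) and Rpl19 at -1.49 (SE 0.50). NRF2 and oxidative stress genes were lower in 37 of 42 (median -0.36, adjusted p = 2.83e-07; adjusted p = 0.64 with an estimated correlation). Among them were the thioredoxin gene Txn1 (-3.30, SE 1.08), the cystine transporter gene Slc7a11 (-1.36, SE 0.38), Akr1b8 (-1.71, SE 0.39) and Gstm1 (-2.71, SE 0.82). Downward shifts were also called for oxidative phosphorylation (-0.36, 37 of 40, adjusted p = 0.000215), glycolysis and hypoxia (-0.33, 25 of 32, adjusted p = 0.00188) and proliferation (-0.09, 36 of 49, adjusted p = 0.000985). These had adjusted p = 0.70, 0.65 and 0.55 with an estimated correlation. Chaperone and immediate early genes (-0.14, 20 of 25, adjusted p = 0.00731), skeletal muscle (-0.38, 25 of 34, adjusted p = 0.02) and extracellular matrix (-0.23, 26 of 34, adjusted p = 0.0265) shifted downward too, with adjusted p = 0.55, 0.71 and 0.71 with an estimated correlation. Examples were the glucose transporter gene Slc2a1 (-0.92, SE 0.21), Hif1a (-1.03, SE 0.40), Eno1 (-0.74, SE 0.27), Top2a (-0.79, SE 0.21), Cenpe (-0.52, SE 0.12), Mki67 (-0.95, SE 0.28), Hspa8 (-2.78, SE 0.85) and Hspa5 (-1.32, SE 0.37). Adipocyte markers (0.32, 17 of 19 higher, adjusted p = 0.000985), thyroid, airway and salivary gland markers (0.17, 17 of 19, adjusted p = 0.0153) and nerve and Schwann cell markers (0.12, 15 of 17, adjusted p = 0.0285) shifted upward, with adjusted p = 0.70 for each with an estimated correlation. The thyroid and airway list (medians per array 4.3 to 4.6) and the nerve list (4.5 to 4.9) lay below the table's median of 4.98 on every array. Their shifts are thus small shifts at low signal. Cfd was at 0.40 (SE 0.16) and Adipoq at 1.95 (SE 1.01), and without riboflavin-deficient neoplasia replicate 1 the adipocyte median was 0.01.

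Other genes of lowest unadjusted p were lower in riboflavin-deficient neoplasia, namely the hyaluronan receptor gene Cd44 (-2.70, SE 0.48), Cyld (-1.42, SE 0.24), the RUNX partner gene Cbfb (-1.52, SE 0.23), Erp44 (-1.22, SE 0.18), Rad23b (-1.33, SE 0.23), Stam (-0.96, SE 0.16), Snora20 (-2.64, SE 0.42), Acp1 (-1.67, SE 0.44) and the NF-kB subunit gene Rel (-1.31, SE 0.34). Pex19 (1.96, SE 0.31) and Pkhd1 (0.79, SE 0.16) were higher. The control separation was lower in the riboflavin-deficient neoplasia group, by a difference of -0.087. That measure was added as a covariate after the data were seen. The ribosomal median was then -0.12 (adjusted p = 0.0599), the squamous median -0.20 (adjusted p = 0.127), the stress keratinocyte median -0.45 (adjusted p = 0.0485), the NRF2 median -0.14 and the glycolysis median -0.03. Of these 5 only the stress keratinocyte list was called. The oxidative phosphorylation, skeletal muscle and extracellular matrix medians turned to 0.23, 0.37 and 0.20 and were called upward. The calls of the nerve, thyroid and airway, and chaperone lists were lost with the covariate, whereas basal keratinocyte (-0.26), proliferation (-0.16) and adipocyte lists kept theirs. Cyclic loess and quantile normalisation each ended the calls of 7 lists, namely oxidative phosphorylation, glycolysis and hypoxia, chaperone genes, skeletal muscle, extracellular matrix, thyroid and airway, and nerve. Those 7 and proliferation were not called in the upper 50 percent of genes by mean.

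By limma 0 genes passed between the diets in neoplasia (lowest adjusted p = 0.851), and 1122 lay at an unadjusted p under 0.05 (391 higher, 731 lower; 1105 by chance). Camera called 14 lists, 0 with an estimated correlation and 0 by fry. Without riboflavin-normal neoplasia replicate 2, 2 genes passed, the stress keratin gene Krt17 (-5.33, limma adjusted p = 0.0439) and Mir330 (-4.69, limma adjusted p = 0.0176), both named after their values were seen. The number of lists called was 5 without riboflavin-normal neoplasia replicate 1 and 9 without riboflavin-deficient neoplasia replicate 2. The former ended the basal keratinocyte (-0.32), stress keratinocyte (-0.19) and proliferation (-0.07) calls among others. Without riboflavin-deficient neoplasia replicate 1 the stress keratinocyte (-0.60), skeletal muscle, nerve and adipocyte calls were lost, and the squamous median was -0.47. Basal keratinocyte and adipocyte medians were -0.19 and 0.50 without riboflavin-deficient neoplasia replicate 2. Without riboflavin-normal neoplasia replicate 2 the NRF2, oxidative phosphorylation and nerve medians were -0.20, -0.17 and 0.20, all called.

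In adjacent normal tissue, the riboflavin-deficient group had lower values of stromal and muscle genes and higher values of squamous genes than the riboflavin-normal group. Extracellular matrix genes were lower in 30 of 34 (median -0.76, camera adjusted p = 4.91e-12; adjusted p = 0.62 with an estimated correlation), with Col1a1 at -0.76 (SE 0.28) and Postn at -0.88 (SE 0.32). Smooth muscle markers were lower in 16 of 16 (median -0.92, adjusted p = 3.01e-08; adjusted p = 0.62 with an estimated correlation), with the calponin gene Cnn1 at -2.51 (SE 1.07). Skeletal muscle markers were lower in 34 of 34 (median -0.80, adjusted p = 2.2e-09; adjusted p = 0.76 with an estimated correlation). Ckmt2 was at -1.12 (SE 0.41), Myh1 at -2.06 (SE 0.89) and Acta1 at -1.36 (SE 0.68). Squamous genes were higher in 37 of 49 (median 0.48, adjusted p = 6.25e-05; adjusted p = 0.76 with an estimated correlation). Filaggrin, Flg, was at 3.12 (SE 0.81), Sprr1b at 2.18 (SE 0.62) and Csta at 2.43 (SE 1.12).

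Oxidative phosphorylation (-0.48, 35 of 40 lower, adjusted p = 2.04e-08) and ribosomal protein genes (-0.27, 44 of 51 lower, adjusted p = 0.000711) shifted downward, with adjusted p = 0.76 for both with an estimated correlation. The respiratory chain genes Ndufc2 and Uqcrb were at -0.98 (SE 0.43) and -1.22 (SE 0.57). Macrophage and monocyte markers also shifted downward (-0.17, 16 of 21 lower, adjusted p = 0.0397). Cytokines and chemokines (0.18, 26 of 36 higher, adjusted p = 0.00682) and stress keratinocyte genes (0.39, 13 of 17 higher, adjusted p = 0.01) shifted upward. These 3 lists had an adjusted p = 0.62 with an estimated correlation. Examples were Il1a (0.74, SE 0.21), Ccl22 (0.38, SE 0.13), Gjb2 (1.10, SE 0.41) and Serpinb2 (1.08, SE 0.44). Elovl6 (1.23, SE 0.20), Birc5 (0.83, SE 0.18) and Nrgn (0.56, SE 0.13) were higher. Chodl (-1.12, SE 0.14), Rnase1 (-1.25, SE 0.18), the muscle filamin gene Flnc (-1.47, SE 0.30), Mrpl53 (-1.49, SE 0.28), and the T cell genes Il7r (-0.60, SE 0.14) and Trat1 (-0.67, SE 0.14) were lower. The T and NK cell list as a whole was not called, with 13 of 26 members higher and a median of 0.03 (camera adjusted p = 0.384).

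The riboflavin-normal adjacent normal arrays stood farthest apart, correlating at 0.916 and separating their controls by 0.577 and 0.757. Without replicate 2 of that group the skeletal muscle, oxidative phosphorylation and ribosomal medians turned to 0.07, 0.07 and 0.53, and extracellular matrix and smooth muscle stood at -0.11 and -0.16. Of these 5 only the ribosomal list was called, and upward (adjusted p = 1.29e-11). Cytokines (0.09) and macrophage markers (-0.05) lost their calls there too. Without replicate 1 the squamous median turned to -0.06, the cytokine and stress keratinocyte (0.12) calls were lost, and 49 genes passed limma, 46 of them lower. The extracellular matrix list held 7 of the 49, including Dcn (-5.52, limma adjusted p = 0.0492), Fn1 (-4.42, limma adjusted p = 0.0355) and Col3a1 (-3.00, limma adjusted p = 0.0283), named after their values were seen. Without replicate 2 only Mir653 passed (-6.88, limma adjusted p = 0.0384). The squamous median was 1.26 there and 1.07 without riboflavin-deficient replicate 2. Without riboflavin-normal replicate 1 the skeletal muscle, smooth muscle, extracellular matrix, oxidative phosphorylation and ribosomal medians were -1.73, -1.96, -1.33, -1.06 and -1.15. Leaving out riboflavin-deficient replicate 1 left skeletal muscle, smooth muscle and ribosomal genes at -1.60, -1.49 and -0.52, and ended the squamous (0.14), stress keratinocyte and macrophage calls, and leaving out replicate 2 of that diet ended the skeletal muscle (-0.05), oxidative phosphorylation (-0.18), ribosomal (-0.04) and cytokine calls, with smooth muscle called at -0.48. Macrophage markers and ribosomal genes were also not called under either further normalisation or the quality covariate (-0.08 and 0.02). In the upper 50 percent of genes the cytokine and macrophage lists were not called. On all arrays 0 genes passed by limma, and 524 lay at an unadjusted p under 0.05 (292 higher, 232 lower; 1105 by chance). Camera called 9 lists, 0 with an estimated correlation and 0 by fry.

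A further 9 genes chosen in advance, of riboflavin handling, inflammation, repair, differentiation and division, did not pass in the mean neoplasia effect. The riboflavin transporter genes Slc52a2 and Slc52a3 were at 0.02 (SE 0.13) and 0.01 (SE 0.12), and the riboflavin kinase gene Rfk at 0.12 (SE 0.19). The neutrophil chemokine gene Cxcl1 was at 0.21 (SE 0.11), Il1b at -0.17 (SE 0.17), the prostaglandin synthase gene Ptgs2 at 0.23 (SE 0.13), the alkyl-DNA repair gene Mgmt at 0.17 (SE 0.14), the suprabasal keratin gene Krt13 at 0.38 (SE 0.60) and Mki67 at 0.23 (SE 0.17). The signs of the values for Slc52a2, Slc52a3, Rfk, Krt13 and Il1b turned when single animals were left out. That of Slc52a3 turned under either further normalisation (-0.01), and that of Mgmt turned with the mean of its probe sets (-0.03). Over the 6 comparisons Slc52a2 ran from -0.06 to 0.22, Slc52a3 from -0.32 to 0.17 and Rfk from -0.43 to 0.33. Cxcl1 ran from 0.06 to 0.24, Il1b from -0.43 to 0.40, Ptgs2 from -0.43 to 0.44 and Mgmt from -0.01 to 0.43. The widest ranges of the 9 were those of Krt13, from -2.27 to 1.52, and Mki67, from -1.36 to 0.91. None of these passed.

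Camera called 11 of the 33 lists in no comparison, and their medians over the 6 comparisons lay between -0.19 and 0.17. These were riboflavin uptake and flavin cofactor synthesis (12 genes, -0.07 to 0.11), flavoenzymes (80 genes, -0.03 to 0.04), NF-kB pathway (25 genes, -0.12 to 0.08), interferon response (26 genes, -0.04 to 0.10), B and plasma cells (14 genes, -0.02 to 0.17), mast cells and eosinophils (20 genes, -0.09 to 0.12), endothelium (20 genes, -0.07 to 0.05), blood cells (15 genes, -0.09 to 0.09), DNA repair (32 genes, -0.05 to 0.08), xenobiotic metabolism (35 genes, -0.02 to 0.06) and fatty acid oxidation (30 genes, -0.19 to -0.01). Their lowest camera adjusted p was 0.0515, for fatty acid oxidation.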

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

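The comparison of the ribosomal and squamous lists with array quality was planned before its result was seen, and the array quality covariate and the slopes with a group left out were chosen only afterwards. A difference between the diets in the neoplasia effect, tested as an interaction, was called for 14 lists and for 5 genes adjusted over their list alone. The list medians were -1.38 for squamous differentiation, -1.45 for stress keratinocyte genes, -0.62 for ribosomal proteins, -0.23 for NRF2 targets, -0.24 for chaperone and immediate early genes, -0.21 for basal keratinocytes, -0.20 for p53 targets, -0.12 for EGFR, Wnt and Notch, and -0.11 for proliferation. They were 0.80 for adipocytes, 0.70 for smooth muscle, 0.38 for extracellular matrix, 0.26 for skeletal muscle and 0.11 for T and NK cells. The genes were Stfa2 (-1.79), Serpinb3 (-1.88), Serpinb2 (-2.55) and Gjb2 (-1.65) in the stress keratinocyte list and Acp1 (-1.87) in the riboflavin list. With an estimated correlation none of the 14 lists was called, the adjusted p running from 0.68 to 0.77.

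The pattern weighed here is the lower ribosomal and squamous signal of riboflavin-deficient neoplasia. This is the diet difference within neoplasia and not the interaction above, for which no prediction from array quality was computed. The predictions below therefore do not carry over to the interaction. Within groups, the ribosomal median moved by 1.32 per 0.1 of control separation, which together with the diets' difference of -0.087 predicts -1.14 (SE 0.08) for the diet difference, against -1.19 observed, so lower array quality may account for the ribosomal shift. The squamous prediction was -0.92 (SE 0.29) against -1.28 observed, which array quality could also account for in large part. Both slopes rest mainly on the riboflavin-normal adjacent normal group, which held 89% of the squared differences in separation. Without that group the predictions were -0.76 (SE 0.10) for ribosomal and -1.78 (SE 0.86) for squamous genes, so the share that quality may account for is imprecise. The predicted and observed differences above are between group means of each array's list median. They are not on the measure of the list values elsewhere, which are medians of the members' differences. On that second measure the ribosomal and squamous values were -0.93 and -0.82, and -0.12 and -0.20 with quality as a covariate. Both arrays of the riboflavin-deficient neoplasia group had lower separation than both of the riboflavin-normal one, so an effect of diet on squamous and ribosomal transcripts stays open and untested apart from quality.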

How the results depend on the processing

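Array quality as a covariate, quantile normalisation of the lists, and the random effect for lists in the diet comparisons were chosen only after the data were seen. In the tissue comparisons the quality covariate left fewer than 2 residual degrees of freedom, so values adjusted for it are imprecise there. With 2 animals per diet, and with a control separation that differed between arrays, small changes are not detectable. A lone array left in a group is assumed to vary like the others. Gene counts past the threshold were 0 in all 6 comparisons and stayed 0 under every alternative, no replicate block (0) among them, except as follows. At an unadjusted p under 0.05 with at least a 2-fold change they were 31 for the mean neoplasia effect, 200 and 72 in the riboflavin-normal and riboflavin-deficient diet, 380 for the difference between diets, 272 between diets in neoplasia and 58 in adjacent normal tissue, through the looser threshold. Leaving out arrays gave 0 to 2 genes between diets in neoplasia and 0 to 49 in adjacent normal tissue. The lists called, in the same order, were 8, 14, 9, 14, 14 and 9. An estimated correlation gave 0 in each, and fry gave 1 in the first and 0 in the others. Removing the block gave 8, 13, 6 and 15 in the tissue comparisons and changed no gene call. The upper 50 percent of genes gave 9 for the difference between diets and 7 for neoplasia, cyclic loess and quantile normalisation gave 4 in the riboflavin-deficient diet and 8 between diets in neoplasia, and the quality covariate gave 9 in the last. Leaving out animals or arrays gave 7 to 13, 14 to 15, 4 to 9, 11 to 15, 5 to 15 and 6 to 13 lists. Of 748 list alternatives 429 kept direction and call, 289 lost the call and 30 reversed. Of 2323 for named genes 2311 kept direction and side of the threshold, 11 reversed, and Cnn1 changed side (-4.38, with a lone array left in a group). As no gene passed in the main fits, keeping the side of the threshold was nearly fixed in advance. Many named genes were picked for a shared sign or a low p, which also favours a kept direction. The gene counts thus say little about robustness. No list count was computed with animal as a random effect for the tissue comparisons. The causes of the reversals were not tested.

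Leave-out medians of lists that reversed ran as follows. For the mean neoplasia effect they were 0.00 to 0.77 for squamous, -0.59 to 0.12 for extracellular matrix, -0.79 to 0.01 for smooth muscle and -0.50 to -0.02 for oxidative phosphorylation. In the riboflavin-normal diet they were -0.06 to 0.43 for basal keratinocytes, -1.23 to 0.19 for extracellular matrix, -1.99 to 0.03 for smooth muscle, -1.78 to 0.00 for skeletal muscle, -0.77 to 0.14 for oxidative phosphorylation and -0.38 to 1.05 for ribosomal proteins. In the riboflavin-deficient diet they were -0.91 to 0.16 for squamous, -1.27 to 0.24 for skeletal muscle and 0.00 to 0.53 for adipocytes. For the difference between diets they were -0.85 to -0.02 for basal keratinocytes, -0.28 to 1.25 for extracellular matrix, -0.09 to 1.61 for smooth muscle, -0.42 to 1.09 for skeletal muscle and -1.37 to 0.13 for ribosomal proteins. Between diets they were 0.01 to 0.50 for adipocytes in neoplasia, and in adjacent normal tissue -0.06 to 1.26 for squamous, -1.73 to 0.07 for skeletal muscle, -1.06 to 0.07 for oxidative phosphorylation and -1.15 to 0.53 for ribosomal proteins. Where a median kept its sign, camera's direction was what reversed. With the quality covariate, neoplasia medians were 0.20 for extracellular matrix, 0.37 for skeletal muscle, 0.00 for thyroid and airway markers and 0.23 for oxidative phosphorylation, and ribosomal proteins in adjacent normal tissue stood at 0.02. Quantile normalisation left skeletal muscle at -0.30 in neoplasia with camera's direction up. For genes in the mean neoplasia effect, leave-outs gave -0.09 to 0.13 for Slc52a2, -0.06 to 0.08 for Slc52a3, -0.12 to 0.37 for Rfk, -0.41 to 1.17 for Krt13 and -0.36 to 0.02 for Il1b. Slc52a3 was -0.01 with cyclic loess and with quantile normalisation, and Mgmt -0.03 as the mean of its probe sets. Adipoq in the riboflavin-deficient diet ran from -0.16 to 3.79.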

Other observations

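Of the tests in this part, the test of muscle wall, the slopes with a group left out and the comparison with the spread of the pairs were chosen only after the result was seen. Some further genes had the same sign in all 4 pairs although none passed over all genes. Ogfrl1 was 0.75 higher in neoplasia (SE 0.13, pair values 0.42 to 0.89), and the monocyte chemokine gene Ccl2 was 0.89 higher (SE 0.19, 0.39 to 1.67). The nucleosome-binding gene Hmgn2 was at -0.70 (SE 0.12, pair values -1.01 to -0.55), the ubiquitin ligase gene Wwp1 at -0.66 (SE 0.11, -0.87 to -0.55) and Ndrg2, a differentiation-associated gene, at -0.76 (SE 0.11, -0.92 to -0.50). The kinase gene Pdk4, which limits the entry of pyruvate into the citric acid cycle, was at -1.08 (SE 0.38) and the glucose transporter gene Slc2a1 at 0.49 (SE 0.14), neither of which passed. Stfa2l3, a stefin like Stfa2, was at 1.27 (SE 0.24, pair values 0.33 to 2.52), and the envelope gene Lce1e at 1.25 (SE 0.38).

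S100a8 and S100a9 were higher in neoplasia in every pair, by 1.62 as the mean of both (SD of the pairs 0.47). The slope on array quality predicts -0.02 (SE 0.02), and -0.03 (SE 0.06) without the riboflavin-normal adjacent normal group. The tissues differed in mean separation by only 0.004, since the pair differences cancel, so this prediction alone decides nothing. By pair, read after the result was seen, the separation differed by 0.119, -0.063, -0.042 and 0.002. Both genes were higher in neoplasia whether separation rose, fell or hardly changed, which argues against array quality as measured here. Neutrophils in the neoplasia samples could raise both genes, but the median of the 5 other neutrophil markers above the table's median was 0.01, 0.26, 0.13 and -0.13 in the pairs, 0.26 at most. None of these 5 had a mean of 7 or more, so their low level keeps neutrophils open, and 3 of the 23 list entries, S100a8 and S100a9 among them, are in another list. A change of the epithelium itself, such as the stress keratinocyte state that shares both genes, stays open as well.

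Skeletal muscle markers had a lower mean in neoplasia for all 34 members, with an observed difference of -0.55 in the list's median (SD of the pairs 0.98). The slope on array quality predicts 0.04 (SE 0.02), and 0.12 (SE 0.02) without the riboflavin-normal adjacent normal group. Control separation differed between tissues in both directions over the pairs, so this prediction is near 0 by cancelling. The observed difference has an SE of 0.49 over the pairs and lies within its own spread, so a prediction below it excludes nothing, and array quality stays open. More muscle wall in the adjacent normal samples is a candidate explanation, since the rat oesophagus has a striated muscle coat. The median of the 17 abundant members was below 0 in 3 of 4 pairs, at 0.00 (just below 0), -1.74, -1.24 and 0.56, and a larger share of muscle in some pairs cannot be told apart from a change within the tissue on 4 pairs.

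Other assignments of the tissues to the arrays bear on how far chance can be excluded. With animals kept as a block there are 8 ways to split the pairs, too few for a share under 0.05. These fits had 1 neoplasia term for both diets in place of 1 per diet, so their counts for the real split can differ from those of the comparisons. The real split called 8 lists and the highest other 14, and 7 of the 8 splits called as many. For genes at an unadjusted p under 0.05 the real split gave 480 and the highest other 2024, and all 8 gave as many. Without the block, and with a mean for each side only, 23 of 35 splits called as many lists as the real one (9, highest other 17) and 34 gave as many genes (337, highest other 6640), so chance is not excluded for either. The split with 6640 genes is many times the real count, which points to a structure of the arrays. Its sides differed in control separation by 0.104 in absolute value. In the real split the difference was 0.004, neoplasia minus adjacent normal tissue.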
